A study of Mus musculus with 2 samples.

How the data were processed

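RNA from whole limb buds of E10.5 mouse embryos, staged by day of gestation, was hybridised to Affymetrix Mouse Genome 430 2.0 arrays, 1 array of wild-type and 1 of Bhlha9 knockout tissue. Per the labels' protocols, total RNA was extracted with ISOGEN and 200 ng of it was reverse-transcribed and biotinylated with a 3′ IVT kit. Per the series' design text, the signals were summarised with MAS 5.0, and the deposited values are these intensities on a linear scale, with 1 signal per probe set. Such a method reads both perfect-match and mismatch probes of a probe set and scales each array on its own, so signals near zero are noisy and a difference in composition between samples shifts all other genes slightly. The 2% trimmed mean over all probe sets came to 500.0 on both arrays. How many embryos gave each RNA, whether fore and hind limb buds were mixed in equal amounts, and how the animals were matched are not given in the sources used here.

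The arrays held 45101 probe sets. The 64 control probe sets were set aside, which left 45037. Gene symbols came from the platform annotation, checked by Entrez identifier against RefSeq genes of the GRCm38.p6 assembly. A single symbol was given for 34945 probe sets, of which 34741 matched and 204 did not, with 0 renamed. A further 932 had several symbols and 9160 were unnamed here, and neither kind was used for genes. No coordinates are given, because the assembly was used only for names and neighbours.

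A floor was set at the 40th percentile of each array's non-control probe sets, 41.2 on the wild-type and 41.8 on the knockout array, and lower signals were raised to it. Of 142 probe sets of genes not expected in a limb bud, such as olfactory receptors, 4.93% and 7.75% lay above the floor. Each gene was represented by its single-symbol probe set with the highest mean signal, which gave 18193 genes, 13088 above the floor on at least 1 array and 11491 on both. The log2 ratio is knockout minus wild-type. Where 1 array was at the floor the ratio is a bound, written as at least N-fold, and where both were no ratio was given. Each group is 1 array, so no p-value or standard error for the genotype was computed, and the number of arrays limits the precision. Genes were counted at a threshold of 2-fold.

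For each gene list, the median log2 ratio over detected members was set among 10000 random lists of the same size, matched on 10 bins of mean log2 signal. A list stood apart below the 2.5th or above the 97.5th percentile, and lists with fewer than 5 detected genes were given values only. The lists, the rule for named genes, the floor and the alternatives were fixed before the data were examined. Named genes were Bhlha9, 13 core limb bud genes, the 10 largest ratios in each direction among genes detected on both arrays with a mean signal of at least the 60th percentile, the 5 largest bounds in each direction, and up to 4 members of each list with the largest ratios detected on both arrays. Clone-named and Y-linked genes were passed over in the rankings, which left out 1 gene. Of 151 named genes, 59 were detected on both arrays and had further probe sets above the floor, and for 46 of them all of these had the same sign. Where few members of a list passed 2-fold, those outside this rule were named after their values were seen, as were Sox10, Ptch1, Gli1, Prrx1, Neurod1, Neurog2, Pax6 and Foxa2. A set of 7 further lists for tissues near the limb bud was written after the data were seen.

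Measurement error was read from the disagreement of the brightest pair of probe sets of 5440 genes, which had a robust SD of 0.396 for the difference, or 0.28 for 1 ratio. The signs matched for 69.4% of these genes and r across genes was 0.507. Among the 175 whose brightest probe set passed 2-fold, 86.9% had the same sign in the next one and 36.6% also passed 2-fold there. The steps were tested on simulated data with this error. True 3-fold differences were called in 93.9% of higher and 97.0% of lower genes, 5-fold differences in 100% of both, 1.5-fold differences in 2.94%, and 7 of 12284 unchanged genes were called. The changed genes were drawn from genes of higher signal detected on both arrays, and every gene was given the same error. On the deposited arrays, the robust SD of the log2 ratio was 0.595 in the fifth of genes with the lowest signal. It was 0.332 in the fifth with the highest, and both values include any true differences. The simulated rates therefore do not give the rate of false calls at low signal. Of 200 simulated lists of unchanged genes, 6% lay outside the central 95%. Alternatives covered median centring, quantile and loess normalization, other floors or a pseudocount of 32, other choices of probe set, and other fold thresholds. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used, and R 4.3.3 with limma 3.58.1 for normalization.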

Results

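Gene expression was measured in whole limb buds of wild-type and Bhlha9 knockout mouse embryos of the C57BL/6 strain at E10.5, with 1 array per genotype. Bhlha9 encodes a basic helix-loop-helix transcription factor, and copy number gains or mutations at the human gene have been tied to split hand/foot with long bone deficiency and to syndactyly. The comparison addresses which limb bud transcripts differ when the gene is missing. Each array carried 45101 probe sets, of which 64 were controls, and its 2% trimmed mean signal was 500.0. Median signals were 79.6 on the wild-type array and 77.3 on the knockout array, and the floors under which a signal was treated as not detected were 41.2 and 41.8. There were no replicates, so no test of the genotype was possible, no value carries a biological error, and "higher" and "lower" describe these 2 arrays. A reading of measurement error within the arrays came from 5440 genes with 2 or more detected probe sets, whose disagreement corresponds to an SD of 0.28 for 1 log2 ratio. This error leaves out differences between embryos, dissections and RNA preparations.

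The targeted gene was read first. The single probe set of Bhlha9 gave 7.87 on the wild-type array and 1.70 on the knockout array, both under the floor, so it did not check the labels in either direction. Whether this probe set lies in the deleted part of the gene was not analysed here.

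Of 13088 genes detected on at least 1 array, 543 were at least 2-fold higher on the knockout array and 347 at least 2-fold lower. The higher genes included 213 that were at the floor on the wild-type array, against 59 lower genes that were at the floor on the knockout array. Differences of 4-fold or more were found for 99 higher and 8 lower genes, and of 8-fold or more for 28 higher and 0 lower genes. Higher genes made up 61.0% of the calls with the deposited scaling, 77.2% after median centring and 71.2% after loess. With the floor at the 60th percentile the share was 50.5%, at a threshold of 1.5-fold 49.0% and among genes of higher signal 47.4%, so the excess of higher genes was not found at those settings. Median centring moved the median log2 ratio of all genes detected on both arrays from -0.01 to 0.13, and the ratios given here are on the deposited scale. Across the genes detected on both arrays, the log2 signals correlated with r = 0.966, and genes are not independent replicates. An alternative chosen after the data were seen left out the genes of the lists of liver, nerve, muscle, somite, blood and other tissues. With it, 481 higher and 345 lower genes were left. These lists hold chosen genes only, so other transcripts of the same tissues may be among the genes left.

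**Figure D1:**
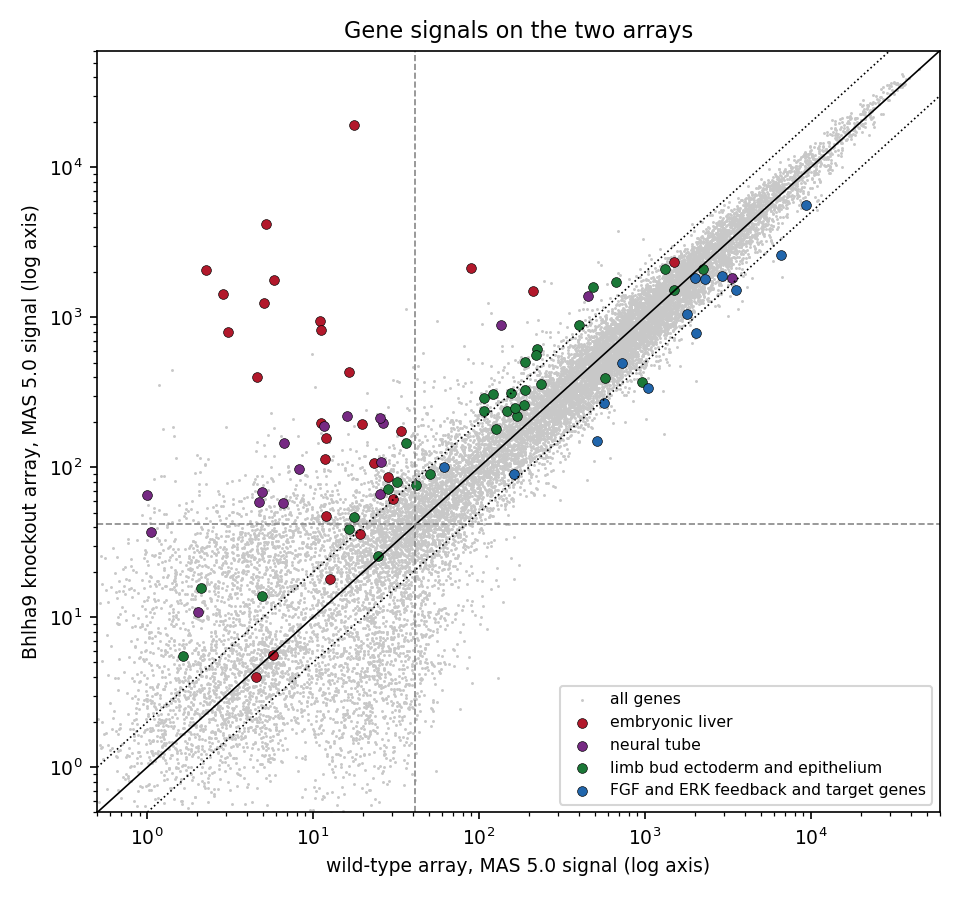
Signal of each gene on the wild-type array (horizontal, MAS 5.0 signal, log axis) against the knockout array (vertical, same unit, log axis), with dashed lines at the floors of 41.2 and 41.8, dotted lines at 2-fold, and 4 gene groups in colour. Most liver genes lie at or under the wild-type floor and well above the knockout floor. Most neural tube genes lie under the wild-type floor too, but several are only a little above the knockout floor. Epithelial genes lie mostly above the diagonal, and 13 of the 14 FGF and ERK genes lie below it.

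The largest differences were transcripts of embryonic liver, most of them under the floor on the wild-type array and detected on the knockout array. Afp, the fetal serum protein, read 17.7 on the wild-type array and 19084 on the knockout array, at least 463-fold higher, and the 3 other probe sets for it above the floor were higher too, 1 of them with a detected wild-type signal of 119.9 against 18222. Ttr, a thyroxine carrier, was at least 101-fold higher by its brightest probe set. A further Ttr probe set, detected on both arrays, gave a smaller log2 ratio of 5.53, from 61.1 to 2819. Alb, encoding albumin, was at least 50.3-fold higher, Ambp at least 42.9-fold and the protease inhibitor Serpina1b at least 34.6-fold. The brightest probe sets of Afp, Ttr and Serpina1b are of a kind prone to cross-hybridisation. The apolipoprotein Apoa2 was detected on both arrays and was 24.0-fold higher, and the retinol carrier Rbp4 was 7.10-fold higher. On a list of embryonic liver genes written after the data had been seen, 20 of 23 detected genes were at least 2-fold higher and 0 lower, with a median log2 ratio of 3.28. That median takes 20 genes at their lower bound, because they were at the floor on the wild-type array, and 13 of the 50 highest ratios of all genes belonged to this list.

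Among genes of higher signal detected on both arrays, the largest ratios after Apoa2 were those of Fabp7, a fatty acid binding protein of radial glia, at 16.9-fold, Reln, a secreted guidance protein of the nervous system, at 10.9-fold, and Mylpf, a skeletal muscle myosin light chain, at 8.98-fold. They were followed by Car3 at 8.64-fold, Rbp4, the ephrin receptor Epha3 at 7.01-fold, the neural progenitor factor Sox2 at 6.52-fold, Hoxc5 at 6.24-fold and the antisense transcript Hoxb5os at 5.49-fold. At the other end stood Macroh2a3 at 7.88-fold lower, from a probe set prone to cross-hybridisation, Cyp26b1, which breaks down retinoic acid, at 5.44-fold lower, and H3f3b at 4.85-fold lower. Lmo1 was 3.96-fold lower, the dorsal determinant Lmx1b 3.79-fold, the smooth muscle actin Acta2 3.61-fold, Kank4 3.24-fold, the matrix protein Fbln1 3.12-fold and the FGF feedback inhibitor Spry2 3.09-fold. Gadd45gip1 was 3.45-fold lower by its brightest probe set, whereas its other detected probe set gave a log2 ratio of 0.32. Genes at the floor only on the knockout array were lower by at least 4.21-fold for Atg16l2, 3.90-fold for Plxnb3, 3.74-fold for Fas and 3.48-fold for Stag3. Wdcp was lower by at least 3.92-fold, but its other detected probe set gave 0.62 in the opposite direction.

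Neural genes formed the group with the highest median among the 32 gene lists fixed before the data were examined. Of 15 detected neural tube genes, 9 were at least 2-fold higher and 0 lower, and the median log2 ratio of 1.39 exceeded all 10000 random lists matched on expression. This median is a lower bound, since 12 of the genes were at the floor on the wild-type array, among them Neurod1 (221 on the knockout array), Neurog2 (214) and Pax6 (146), all regulators of neuronal fate. These 12 were detected through the knockout array alone, so their ratios could only be positive. The random lists were not matched on this, so the rank of the median partly reflects how members were selected. Only 3 members were detected on both arrays, with a median of 1.60. The neural tube median was 0.35 with the floor at the 60th percentile and 3.14 without a floor, and the list stood apart at both settings. Sox2 and Zic1 were detected on both arrays, at log2 ratios of 2.71 and 1.60. Irx3, which limb mesenchyme also expresses, was at -0.88. In the list of neural crest, glia and nerve genes, 8 of 14 were at least 2-fold higher and 0 lower, with a median of 1.31. The neurofilament genes Nefl and Nefm were 7.91-fold and 6.49-fold higher, and the axonal genes Stmn2 and Tubb3 were 6.14-fold and 4.81-fold higher. Of the 14 ratios 10 were positive and 4 negative, the glial factor Sox10 going from 76.6 to 46.5, and Ngfr and the neuronal gene Dcx, both named after their values were seen, standing at -0.57 and -0.54.

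Muscle and somite genes were also higher. Among 17 muscle genes, 5 were at least 2-fold higher and 0 lower, with a median of 0.79. The myosin light chain Myl4 was 11.1-fold higher, the troponin Tnnt2 4.70-fold, and the myogenic factors Myog and Myf5 4.15-fold and 2.44-fold. Myod1 was at the floor on the wild-type array and at least 2.17-fold higher. Lbx1, a marker of migrating limb muscle precursors, ran the other way at -0.80. The somite and flank list had 6 of 16 genes at least 2-fold higher and 0 lower and a median of 0.77, with the mesothelial gene Wt1 at 4.03-fold, Foxc2 at 2.71-fold and Upk3b at 2.34-fold. Both lists lay above all random lists.

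Ectodermal and epithelial genes were higher as a group. In the list of limb bud ectoderm and epithelium, 11 of 28 detected genes were at least 2-fold higher and 1 was lower, and 25 ratios were positive. The median of 0.82 lay above all random lists, whose central 95% ran from -0.29 to 0.21. Cdh1, encoding E-cadherin, went from 488 to 1602, a log2 ratio of 1.72, and the epithelial splicing factor Esrp1, the sorting adaptor Ap1m2 and the tight junction gene Cldn7 had ratios of 1.45, 1.43 and 1.41. Tfap2c was the lower gene, at 2.62-fold. This member was named after its value was seen. Of 16 ectoderm genes reported as p63 targets, 4 were at least 2-fold higher, namely Cldn1 (1.63), Dlx5 (1.35), Perp (1.15) and Krt5 (1.01), and 0 were lower, with a median of 0.44 at percentile 99.9. Liver and gut epithelium share many of these transcripts, and the liver genes described above were higher on the same array.

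The apical ectodermal ridge, the signalling epithelium at the limb bud tip, gave a mixed reading. Of 21 detected genes of its list, 6 were at least 2-fold higher and 0 lower, and the median of 0.24 lay at percentile 96.5, inside the central 95% of random lists. Fgf8, the main ridge FGF, read 445 on the wild-type array and 492 on the knockout array, a log2 ratio of 0.15 and within the measurement error. Fgf4 was at 86.9 and 58.8, a ratio of -0.56 near the floor. Sp8, Dlx1 and Dlx5 had ratios of 1.54, 1.54 and 1.35. Trp63, encoding the ectodermal regulator p63, had a ratio of 1.46 by its brightest probe set, while its other 2 detected probe sets gave -0.20 and 0.01. Msx2 had a ratio of -0.24 by its brightest probe set and 0.95 by a dimmer one, and Dlx6 was under the floor on both arrays, at 5.10 and 5.85. The ridge list lay above the random range under 3 of the 9 alternatives, among them loess, with a median of 0.40.

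FGF and ERK feedback and target genes were lower together. Of 14 detected genes, 6 were at least 2-fold lower and 0 higher, 13 had negative ratios, and the median of -0.81 lay below all 10000 random lists. The ETS factors Etv4 and Etv5, transcribed in response to FGF, were 3.43-fold and 2.59-fold lower. The feedback inhibitor Spry2 was 3.09-fold lower, and the LIM homeodomain gene Lhx9 was 2.52-fold lower, at 6593 and 2613. Every further detected probe set of these 4 genes had the same sign. Fgf10, the mesenchymal FGF that sustains outgrowth, was at 162 and 89.7, a ratio of -0.86.

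Limb mesenchyme and distal Hox genes were lower as well. In the mesenchyme list, 5 of 22 genes were at least 2-fold lower and 2 higher, 18 ratios were negative, and the median of -0.62 lay below all random lists. Lmx1b, Tbx15, Msx1, Lhx9 and Shox2 were 3.79-fold, 2.84-fold, 2.59-fold, 2.52-fold and 2.48-fold lower, Tfap2b and Emx2 were 3.33-fold and 2.23-fold higher, and Prrx1, expressed throughout early limb mesenchyme, was at -0.33. In the list of distal HoxA and HoxD genes, whose 10 members include the neighbouring genes Evx2 and Lnpk and the central-group gene Hoxa7, 3 were at least 2-fold lower and 0 higher, with a median of -0.89 below all random lists. Hoxa7, Hoxa11 and Hoxa10 had ratios of -1.22, -1.19 and -1.05, and Hoxd10 of -0.94. Hoxd13 differed by less than the measurement error, at 1448 and 1420.5. Hoxd9 and Hoxa9 of the proximal list were at -1.27 and -0.87, the latter named after its value was seen. Lower Hox readings were thus not particular to distal members. The ratios of these limb genes ran opposite to those of the neural and liver genes on the same array.

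**Figure D2:**
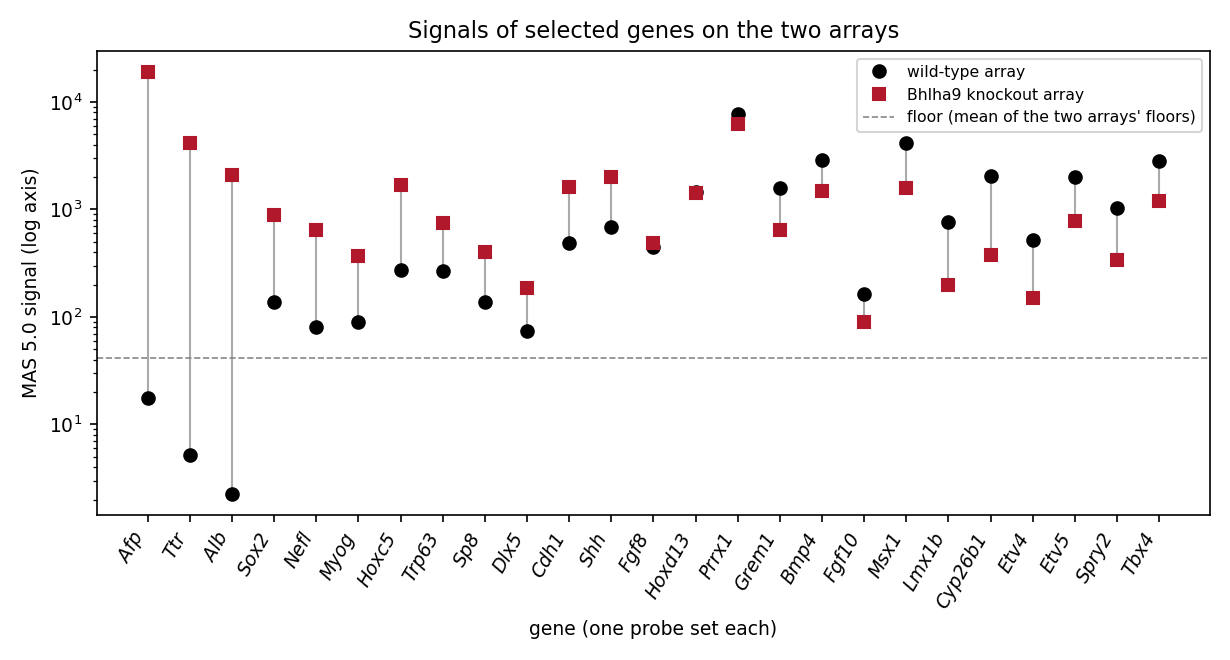
MAS 5.0 signal (vertical, log axis) of selected genes on the wild-type array (black circles) and the knockout array (red squares), 1 probe set and 1 array each, so without error bars, with the mean floor dashed. Afp, Ttr and Alb are under the floor only on the wild-type array, Shh is higher and Grem1 lower on the knockout array, and Fgf8 and Hoxd13 nearly coincide.

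Genes of the sonic hedgehog pathway and the posterior limb bud moved apart from each other. Shh, a signal of the posterior limb bud and also of floor plate and gut endoderm, was 2.87-fold higher, from 693 to 1986. Foxa2, which floor plate and gut endoderm express and which was named after its value was seen, was at least 4.82-fold higher on the same array, so the tissue behind the Shh signal was not resolved. Tbx2 and Foxf2 were 2.43-fold and 2.41-fold higher. Grem1, the BMP antagonist that links posterior signalling to the ridge, was 2.47-fold lower, from 1575 to 638. The pathway genes Ptch1 and Gli1 were at 0.31 and -0.46. The median of the 19 genes was -0.27, at percentile 1.39, although their mean was 0.07, and the list stood apart under 4 of the 9 alternatives. Hhip, which binds hedgehog ligands, was at the floor on the wild-type array and at least 3.16-fold higher. With it, 4 genes were at least 2-fold higher, against Grem1 alone in the lower direction.

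BMP and proximal limb genes also split. Bmp4 was 1.92-fold lower, from 2862 to 1489, and Msx1 was lower, while Id4 was 2.14-fold higher. The BMP list had a median of 0.23 at percentile 97.6 and a mean of 0.08, with 2 of 19 genes at least 2-fold higher (Id4 and Tbx2) and 2 lower (Msx1 and Grem1), and it did not stand apart under any of the 9 alternatives. Among 13 proximal limb genes, the retinoic acid synthesising enzyme Aldh1a2 was 2.78-fold higher, Emx2 was 2.23-fold higher, and Cyp26b1, Shox2 and Hoxd9 were 5.44-fold, 2.48-fold and 2.41-fold lower. Their median of 0.27 was positive and their mean of -0.17 negative, and with unique probe sets alone the median was -0.87. The Wnt list of 23 genes had a median of -0.12 at percentile 24.0, with 0 genes at least 2-fold higher and 2 lower, namely Nkd2 (-1.04) and Wif1 (-1.01), while Lgr5 stood at 0.99 and Sp5 at -0.85.

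The limb identity factors Tbx4, Pitx1 and Tbx5 had negative ratios, whereas several Hox genes of the forelimb list had positive ones. The hindlimb genes Tbx4 and Pitx1 were 2.35-fold and 2.10-fold lower, and the forelimb gene Tbx5 had ratios of -0.60 and -1.33 by its 2 probe sets. The hindlimb list of 5 detected genes had a median of -0.69 at percentile 0.25, which moved to -0.33 without a floor, inside the random range. Hoxc10 was at -0.69, and Isl1, which motor neurons express as well, was 3.45-fold higher. The forelimb list of 7 genes had a median of 0.28 at percentile 93.2, with Hoxc5 (2.64) and Hoxc4 (1.497) as its highest members, while Hoxc6 was at 0.36 by its brightest probe set and negative by its other 2.

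None of the 4 lists tied to later limb patterning, human limb malformations and basic helix-loop-helix factors stood apart. Sox9, the regulator of cartilage condensation, was at 713 and 599, a ratio of -0.25, with -0.81 by its other detected probe set. The chondrogenic list had 0 of 12 genes past 2-fold and a median of -0.19 at percentile 14.9, with Sox5 (-0.69), Hapln1 (0.68), Col2a1 (0.64) and Wwp2 (-0.51) farthest from zero among genes detected on both arrays. The list of interdigital and syndactyly-associated genes had 1 of 22 at least 2-fold higher and 3 lower, with 16 negative ratios, a median of -0.19 at percentile 8.35 and a place below the random range under 1 of the 9 alternatives. Its higher gene was Aldh1a2, and its lower genes were Msx1, Rarg (-1.22) and Adamts5 (-1.13). The split hand/foot list had 2 of 11 genes higher, Trp63 and Dlx5, and 0 lower, with a median of -0.02 at percentile 62.5, and Poll (-0.96) and Lbx1 as its lowest members. The basic helix-loop-helix list had 3 of 21 genes higher, Tcf21 (1.73), Hey2 (1.35) and Id4 (1.10), and 0 lower, with a median of -0.02 at percentile 32.2 and a mean of 0.16. Scx was at 0.91, and the list lay below the random range under 1 of the 9 alternatives.

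Endothelial genes were lower, and red cell genes slightly higher. In the endothelial list, 18 of 20 ratios were negative, 2 genes were at least 2-fold lower (Kdr and Tie1) and 0 higher, and the median was -0.42 at percentile 0.45. The VEGF receptor genes Kdr and Flt1 were at -1.09 and -0.71, Eng at -0.84 and Pecam1 at -0.71. The primitive red cell list had a median of 0.32 at percentile 98.0, with 1 of 12 genes at least 2-fold higher, the erythroid factor Klf1 (1.02), and Hemgn, Rhag and Slc4a1 at 0.73, 0.58 and 0.55. It stood apart under 5 of the 9 alternatives. Leukocyte genes had a median of -0.16 at percentile 16.7, with 1 of 14 higher (Lyve1) and 1 lower (Cx3cr1). Mrc1 and C1qb were at 0.91 and 0.81, Csf1r and Ptprc at -0.90 and -0.84, and the other probe sets of C1qb were of opposite sign.

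The cell cycle and matrix lists stood apart on the lower side, under 7 and 6 of the 9 alternatives as well, and the p53 and immediate early lists did not. The cell cycle list had a median of -0.08 at percentile 2.00, with 0 of 30 genes higher and 1 lower, E2f1 (-1.13), and its median was 0.058 after median centring. Ccne2 was at 0.85, Plk1 at -0.77 and Tyms at -0.73. The matrix list had a median of -0.22 at percentile 1.72, 14 of 21 ratios negative, with the glycoprotein Tnc 5.39-fold higher as the only gene past 2-fold, Dcn at 0.84 and the basement membrane collagens Col4a1 and Col4a2 at -0.98 and -0.86. The p53 list had a median of 0.00 at percentile 57.6, with Trp53inp1 (1.27) and Perp higher and Pmaip1 (-1.37) and Fas lower, and Bbc3 at -0.77. Immediate early genes had a median of -0.14 at percentile 23.1, with 1 of 18 at least 2-fold lower, Ier3 (-1.28), and Ier2, Nr4a1 and Egr1 at -0.99, -0.80 and -0.76.

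No gene of the remaining metabolic and stress lists passed 2-fold. Hypoxia and glycolysis genes had a median of 0.02 at percentile 43.6, with Bnip3 (0.70), Ankrd37 (0.62), Pdk1 (0.45) and Pkm (-0.41) farthest from zero among genes detected on both arrays, and Adm at the floor on the knockout array with a bound of -0.94. The heat shock and unfolded protein list had a median of 0.00 at percentile 31.5. Chac1 (-0.86), Ddit3 (0.75), Hsph1 (-0.56) and Herpud1 (-0.41) were farthest from zero among genes detected on both arrays. Another member, at the floor on the wild-type array, had a bound of 0.99. A further probe set of Ddit3, at the floor on the knockout array, gave a bound of -1.08. Other detected probe sets were also of opposite sign for Id4 (-0.25), Nkd2 (0.24), Vps53 (0.12) and Tyms (0.01), and for Rps18 (-0.31, -0.26 and -0.76). Ribosomal protein genes had a median of 0.19 at percentile 87.2, with Rps6 (0.71), Rpl7 (0.33), Rpl11 (0.28) and Rps18 (0.26). The oxidative phosphorylation list had a median of 0.12 at percentile 61.3, with Uqcrc1 (-0.99), Ndufs1 (0.41), Uqcrc2 (0.41) and Ndufa4 (0.38).

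**Figure D3:**
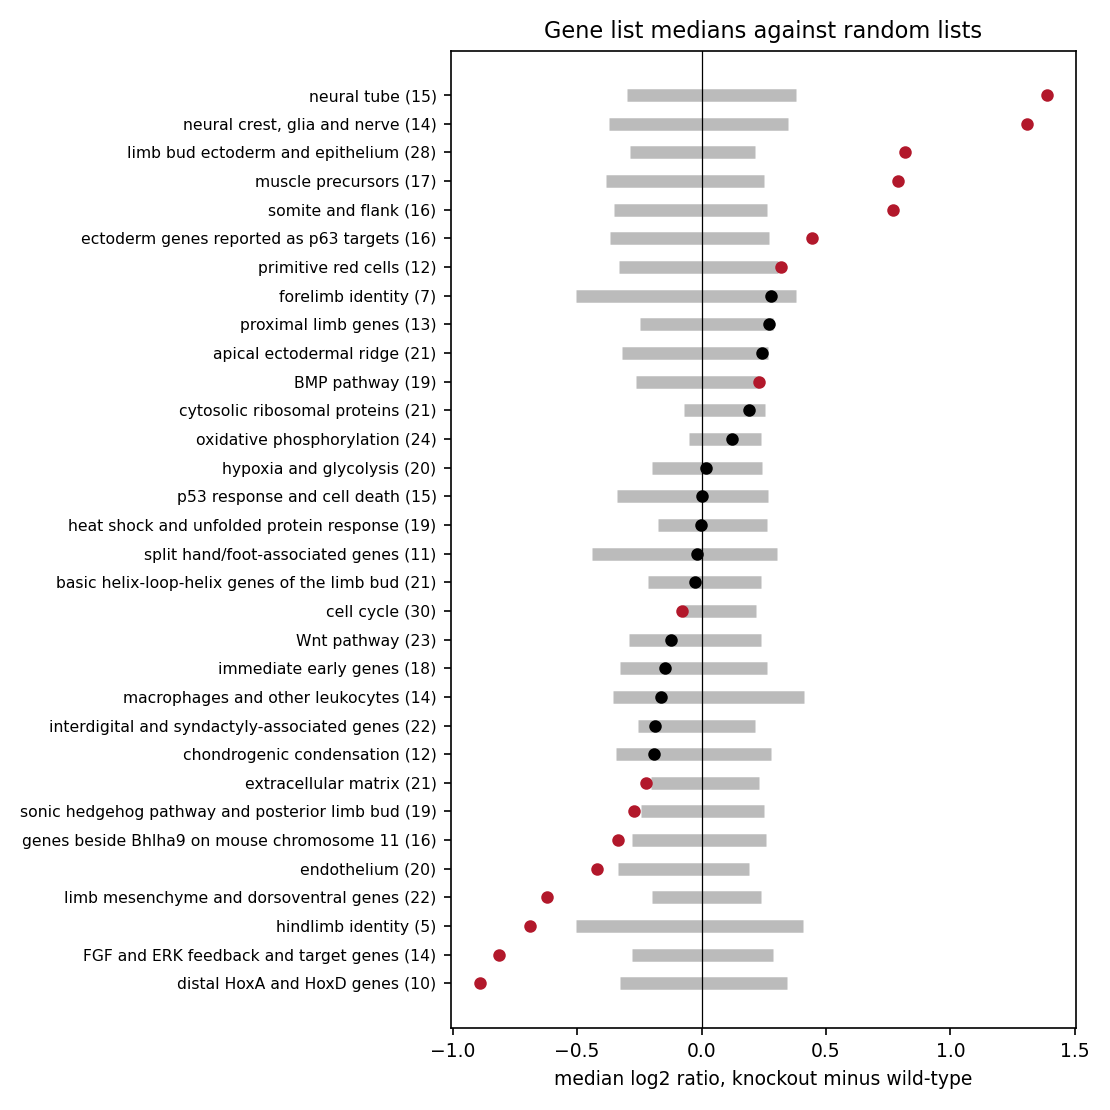
Median log2 ratio, knockout minus wild-type, of each of the 32 gene lists (points, with the number of detected genes in brackets) against the central 95% of 10000 random lists of matched expression (grey bars), red where the median lies outside. The neural tube list is highest at 1.39 and the distal HoxA and HoxD list lowest at -0.89.

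Genes beside Bhlha9 on mouse chromosome 11 had a median of -0.34 at percentile 0.90. Of 16 detected neighbours, 12 had negative ratios, 1 was at least 2-fold higher (Rph3al) and 0 lower. Nxn, Vps53, Myo1c and Inpp5k were at -0.65, -0.61, -0.57 and -0.54 by their brightest probe sets. Another detected probe set of Myo1c gave -0.02. Those of Inpp5k gave 1.01 and, at the floor on the knockout array, a bound of -0.17. With the mean over probe sets the median was -0.16, inside the random range.

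Across the 32 lists, 17 stood apart, 8 above and 9 below, where 1.6 would fall outside by chance if lists of unrelated genes behaved like the random ones. Genes of a list share cells and regulators, so this count describes the arrays and not the genotype. Some lists also share members, such as Fgf10, Lhx2 and Lhx9 in the FGF and ERK and limb mesenchyme lists. The 17 lists are therefore not separate readings. Of the sex-linked genes, Xist read 17463 and 16544 by its brightest probe set, with a log2 ratio of -0.07 by another probe set and -1.11 by a further one, and the Y-linked genes Eif2s3y, Kdm5d and Uty were under the floor on both. The ratio of 3′ to 5′ signal was 1.45 and 1.88 for Actb and 0.925 and 0.848 for Gapdh on the wild-type and knockout arrays, respectively.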

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

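Control probe sets, which enter no comparison, differed between the arrays. The 3 probe sets of 18S ribosomal RNA were higher on the knockout array by a median of 3.82-fold, with a range from 3.54 to 5.17. They were picked out because every one of them differed by more than 2-fold. Poly-A controls, added to RNA before labelling when a kit's spike-ins are used, ran the other way, with a median log2 ratio of -1.13 over 24 probe sets. Hybridisation controls were close to equal, with a median of 0.14 over 18 probe sets.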

How the results depend on the processing

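The 12 processing alternatives planned before the data were examined bear on the results as follows, and 1 alternative was chosen after they were seen. Of the 17 lists that stood apart, 10 did so on the same side under all 9 alternatives of scaling, floor and probe set: ectoderm, p63 targets, FGF and ERK, limb mesenchyme, distal Hox, muscle, endothelium, nerve, neural tube and somite. A further 6 did so under some of the 9, and the BMP list under none. Of 1302 recomputed values of named genes, 0 of those past 2-fold reversed and 120 moved by more than the measurement error. A further 39 could not be given, because both signals were at the floor or the gene had no unique probe set. Of 288 recomputed list medians, 237 moved by less than the spread of random lists. Those that moved further, for lists that stood apart here or under an alternative, and counts that moved by over 1.5 times, are given next.

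With median centring, 216 genes were lower, the cell cycle median reversed to 0.058, and the medians were 0.95 for ectoderm, -0.13 for sonic hedgehog, 0.37 for BMP, -0.48 for limb mesenchyme, -0.048 for interdigital, -0.28 for endothelium, -0.084 for matrix and 0.11 for basic helix-loop-helix genes. These are the shift of all ratios that centring makes. With loess the ridge median was 0.40. Without a floor 2486 genes were higher and 1959 lower, because signals near zero then give large ratios, and the medians were 1.15 for ectoderm, 0.62 for p63 targets, -0.13 for sonic hedgehog, -0.33 for hindlimb and 3.14 for neural tube. With the floor at the 60th percentile 160 were higher and 157 lower, since more genes were raised to it, and the medians were 0.63 for ectoderm, 0.27 for p63 targets, -0.30 for proximal genes, 0.60 for muscle, 0.35 for neural tube and 0.55 for somite. With the floor from genes not expected in limb buds they were -0.13 for sonic hedgehog and 1.60 for neural tube, and with a pseudocount 0.58 for ectoderm, -0.12 for sonic hedgehog and -0.31 for hindlimb.

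Averaging probe sets gave -0.10 for sonic hedgehog, 0.0450 for proximal genes and -0.16 for the neighbours of Bhlha9. Unique probe sets gave -0.080 for sonic hedgehog, -0.87 for proximal genes, 1.49 for nerve and -0.28 for basic helix-loop-helix genes. For other changes of floor and probe set the cause was not tested. By construction, 1472 genes were higher and 1534 lower at 1.5-fold, 175 and 45 at 3-fold, and 91 and 101 among genes of higher signal. Quantile normalization gave 616 and 273. Signal over background limits the neural tube and liver ratios, of which 12 of 15 and 20 of 23 are bounds. No paired analysis was possible because each group is 1 array.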

Other observations

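The tests in this part were chosen after their results had been seen, except those of the yolk sac list, the gut and lung list and the windows of neighbouring genes. Genes of neighbouring organs and of anterior body levels were read with 7 lists written after the data were seen. Anterior Hox genes, groups 2 to 5, were higher on the knockout array, with 4 of 11 at least 2-fold higher, 0 lower and a median log2 ratio of 0.86 above all 10000 random lists. The 4 were Hoxc5 (2.64), Hoxa4 (1.79), Hoxc4 (1.497) and Hoxb4 (1.37), and the forelimb list fixed earlier shares Hoxc4, Hoxc5, Hoxa5 and Hoxb5 with this list. Gut and lung endoderm genes had 3 of 5 detected members at least 2-fold higher, namely the pioneer factor Foxa1 (at least 7.62-fold), Cldn3 and Spink1, all at the floor on the wild-type array, while Gata6 was at 0.26. The mesonephros and urogenital ridge list had a median of 0.35 at percentile 96.8, with Ret (4.98-fold), Gata3 and Emx2 higher and Lhx9 lower.

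Heart genes did not move together. Their median was 0.41 at percentile 88.8, with Myl7, Gata4 and Ttn at least 2-fold higher from the floor, while Tbx20 was 5.27-fold lower, from 613 to 116. The yolk sac list had Lrp2 (1.15) and Muc13 (1.20) as its only genes past 2-fold. Only Six3 and Emx1 of 12 forebrain, midbrain and eye genes were above the floor, in both cases on the wild-type array alone, so no median was set against random lists. Probe sets assigned to no single gene leaned lower, with 2.46% of 5039 detected ones at least 2-fold higher and 7.48% lower, against 3.38% and 3.89% of 24162 probe sets of 1 gene.

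Liver and neural transcripts on the knockout array were weighed first. The scaling of the arrays is argued against as the whole cause by medians that stayed high: the lower of the medians after quantile and loess normalization was 3.26 for the liver list and 1.39 for the neural tube list. The liver list cannot tell RNA of embryonic liver in the knockout sample from other causes. It was written after these genes had been seen to be higher. On it 87.0% of the 23 detected genes were at least 2-fold higher, but 20 of the 23 were detected on the knockout array alone, and of the 3 detected on both arrays Apoa2 (4.59) and Rbp4 (2.83) were past 2-fold and Dlk1 (0.65) was not. The yolk sac, which makes many of the same serum proteins, cannot be told apart as a further source, because its list of 6 detected genes had a median of 0.28 with a spread of random lists of 0.27. By the rule fixed before the data were examined, the 5 largest higher bounds were those of Afp, Ttr, Alb, Ambp and Serpina1b. These bounds do not rest on the liver list, but they cannot tell a tissue source from an effect of genotype. An effect of the missing gene stays open and untested. So does a difference in how much trunk tissue was taken with the limb buds, since each genotype is 1 array.

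Lower FGF, limb mesenchyme and distal Hox genes were weighed next. Scaling is argued against by the FGF and ERK median, which was -0.80 at its highest after quantile and loess normalization. A lower share of limb mesenchyme, as dilution by other tissue would give, stays open. For 19 genes with several detected probe sets, the ratio was averaged over them. The SD between these means was 3.30 times the SD that probe set disagreement would give such means. The 95% bootstrap interval over genes was 1.97 to 5.03. However, incoming tissue that expresses some of these genes, such as Tfap2b, which was higher, would give such a spread too. Fewer hindlimb cells are argued against as the whole cause, since Tbx5 was lower too, with a mean of -0.96 against -1.42 for Tbx4 and Pitx1. The difference was -0.45, with an interval of -0.93 to 0.02 from probe set error, which barely includes zero. By the brightest probe sets Tbx5 was at -0.60, against -1.23 for Tbx4 and -1.07 for Pitx1. The FGF and ERK median of -0.81 fell no more than the Tbx4 and Pitx1 mean, as that cause predicts. Fewer hindlimb cells as a part of the cause stay open. A difference in developmental stage between the embryos and an effect of genotype also stay open, and neither was tested.

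Higher epithelial genes were weighed last, and both tissue explanations stayed open. More surface ectoderm in the knockout sample cannot be told apart from other sources, because the genes read for it were picked after their values were seen. Those 8 ectoderm-restricted genes had a median of 0.92, against 1.25 for 12 epithelial genes shared with gut and liver, while the ectoderm genes Tfap2c and Tfap2a, which were not among them, were at -1.39 and -0.55. Epithelium of gut, lung or liver stays open as well: the gut and lung list had a median of 1.48 over 5 detected genes, but 4 of these were detected on the knockout array alone, and Gata6, the only one measured on both, was at 0.26. An effect of genotype on the ectoderm was not tested.

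A hypothesis that loss of Bhlha9 lowered nearby genes was tested against windows of 16 neighbouring detected genes over the whole genome. A median as low as that of the Bhlha9 neighbours was found in 7.19% of 12759 windows. The reading beside Bhlha9 was therefore not rare among groups of neighbouring genes on these arrays. An effect on only a few of the genes would hardly move such a median. An effect local to that region was thus neither shown nor excluded.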
